A study of Mus musculus with 8 samples.

How the data were processed

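The libraries held nuclear RNA of mouse hippocampal pyramidal cells. The cells had been identified as place cells, neurons that fire at particular locations, by imaging in the living animal during spatial navigation, and their nuclei were then tagged with light and collected. There were 8 wild-type libraries, 4 of Day 0 place cells and 4 of Recurring place cells. The labels name these 2 classes and do not define them further. Each title names a mouse with its own number, and nothing else in the labels says that the libraries came from separate animals. Replicates were numbered in the order of the deposit, so the numbers pair no libraries, and no sex, date or batch is given. Libraries were made with a SMART-Seq mRNA kit. Per the labels, reads were aligned with STAR to GRCm39 and counted per gene with HTSeq, with no versions given.

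The deposited values are a scaled signal per gene and library for 15519 genes, with no log transform. Within each gene, the deposited values were whole reads multiplied by a constant of that gene. The constants matched trimmed-mean-of-M-values factors computed with genes in the place of libraries and Ptdss1 as the reference. The median constant was 1.11, with a 1st percentile of 0.218 and a 99th percentile of 7.72. Dividing the constants out gave whole reads, to a tolerance of 0.1 read, for 95910 of 95910 values above 0, with a largest deviation of 0.063 read. The step was tested on simulated data of 14806 genes, and every read was recovered in 100% of them. The deposited values therefore carried no correction for library depth, and they could not be compared between genes. No gene in the table had values above 0 in fewer than 3 libraries, and whether other genes had been removed cannot be read from the table.

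The plan had been to test the deposited values as they stand, taken as corrected for library depth. Because they were not, the recovered reads were divided by median-of-ratios size factors, which ranged from 0.837 to 1.61, and the planned test was then run without other change. This choice was made after the values were seen, and the deposited values as they stand were tried as an alternative. The groups, tests, gene lists, rule for named genes and first set of alternatives were set before the data were examined. Values below are normalized counts, or log2 of the normalized count plus 1.

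Recurring was compared with Day 0 gene by gene with limma 3.58.1 in R 4.3.3, with a variance trend and the Benjamini-Hochberg adjustment. Genes with a normalized count of 10 or more in at least 4 libraries were tested, 11078 in all, at an adjusted p threshold of 0.05. All differences are Recurring minus Day 0, with limma's standard error. The p values measure only the spread between these 8 libraries.

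In all, 35 gene lists were fixed: 15 of neuronal function, 14 of cell type markers and 6 of library checks. Lists with at least 4 tested members were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists tested. The same lists were tested with a correlation estimated per list and with fry. Marker levels per library were the mean log2 value over a list's members present in the table. Levels and 7 library measures were compared by 2-sided exact permutation over all 70 assignments of the libraries, which gives no p below 0.0286. Similarity was Pearson's r across tested genes for each of the 28 pairs of libraries, with a one-sided exact permutation test over the 35 distinct splits.

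Genes were named by a fixed rule. Had genes passed the threshold, up to 12 per direction with the largest differences and no overlap between groups would have been named. Whatever passed, the rule took the 6 higher and 6 lower genes with the smallest unadjusted p. It also took the tested member of each neuronal function list with the smallest p and of each cell type marker list with the highest mean, and a fixed set of activity and cell type genes. Predicted genes and clones were kept out by symbol, and pseudogenes by symbol or gene type. Gene types came from GENCODE vM21, an annotation of an earlier mouse build than the one the authors used. No position was taken from it. Not every gene that the rule takes is used here. Genes named outside it are said to have been chosen after their values were seen.

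Power was tested on simulated data with 40 changed genes per fold. With the spread of these libraries, 0 of 40 genes were called at 2-fold, 2 at 4-fold, 12 at 8-fold, 23 at 16-fold and 22 at 64-fold, with 5 unchanged genes called. With a small spread, a dispersion of 0.05, 30 were called at 2-fold and 40 at each larger fold, with 6 unchanged genes called. Counts were drawn from a negative binomial model with the spread set on the count scale. Their zeros were not compared with those of the real libraries. All changed genes were set in the same data, which eases the adjustment, so power in the real libraries may be lower.

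The first alternatives were pseudocounts of 0.5 and 5, no filter, a filter on a mean of 50 or more, equal library sums, quantile normalization, no variance trend, a robust variance prior, library weights, the number of genes detected as a covariate and leaving out each library in turn. For single results they were an estimated list correlation, fry, the share of reads in place of the mean log2 level, counting genes detected per library at 10 or more, Spearman correlation and the 500 most variable genes. Those added after the data were seen included the deposited values as they stand, voom on the recovered reads, Y-linked level as a covariate and leaving out Recurring libraries 1 and 2 together.

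Library depth ranged from 8374986 to 14887866 recovered reads over the genes in the table. A count of 0 was given a floor of 3 reads per library. Where a group was at 0 reads throughout, the least fold is the other group's mean count over that floor. It takes no account of the spread between libraries. Shares of reads in a single library carry 95% exact (Clopper-Pearson) intervals. No molecular identifiers are stated, so intervals and floors cover counting error only. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.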

Results

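Nuclear RNA was sequenced from hippocampal pyramidal cells of mice, in 4 libraries of Day 0 place cells and 4 of Recurring place cells. Depth in Day 0 replicates 1 to 4 was 11789782, 10137998, 8374986 and 9766640 reads. In Recurring replicates 1 to 4 it was 14887866, 12234631, 8613854 and 9332710 reads. Genes detected per library averaged 12093.5 ± 1299 (SD, n = 4) in Day 0 and 11884 ± 888 (SD, n = 4) in Recurring cells. The nuclear noncoding RNA Malat1 took 3.23% ± 2.18 of reads in Day 0 and 2.92% ± 0.621 in Recurring cells (SD, n = 4). The neuronal noncoding RNAs Snhg11 and Meg3, chosen after their values were seen as abundant, took 1.94% ± 0.646 and 1.24% ± 0.296 in Day 0 cells. In Recurring cells they took 1.96% ± 0.804 and 1.10% ± 0.314.

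Both groups carried abundant RNA of CA1 pyramidal neurons. The mean log2 level of 14 CA1 pyramidal markers was 9.87 ± 0.43 in Day 0 and 10.03 ± 0.30 in Recurring cells (SD, n = 4). Slc17a7, the vesicular glutamate transporter of these neurons, stood at 11.31 ± 0.61 and 10.98 ± 0.73. Zbtb20, a transcription factor of hippocampal pyramidal neurons, stood at 13.99 ± 0.55 and 14.33 ± 0.56, a difference of 0.34 (SE 0.30). The CA1 genes Wfs1 and Calb1 differed by 0.34 (SE 0.72) and 0.24 (SE 0.57). By limma's camera the CA1 list had an adjusted p of 0.922, with 8 of its 14 tested members higher and 6 lower in Recurring cells.

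The main comparison asked which genes separate place cells labelled Recurring from those labelled Day 0. No single gene did so at the threshold: limma called 0 of 11078 genes, with a lowest adjusted p of 0.981. At an unadjusted p under 0.05 there were 401 genes, 208 higher and 193 lower in Recurring cells, where the other groupings of the 8 libraries into groups of 4 gave a median of 455.5 and 29 of the 35 groupings gave as many. Voom on the recovered reads also called 0, with 506 at an unadjusted p under 0.05. Without a variance trend limma called 2 genes at an adjusted p of 0.0300, a result that depends on that setting. They were A130010J15Rik, different by 7.60, and Gm47033, by -8.61, a RIKEN clone and a predicted gene, both outside the naming rule and chosen after their values were seen.

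The 6 genes higher in Recurring cells with the smallest p all missed the threshold. Itgav, the integrin alpha V subunit, was at 0 reads in the 4 Day 0 libraries and at 6.13 ± 1.20 (log2, SD, n = 4) in Recurring cells. Its mean count there was at least 33.0-fold higher. Dck, deoxycytidine kinase of nucleoside salvage, was at 0 and 6.69 ± 2.56, and Mypop, a transcriptional repressor, at 0 and 6.22 ± 2.16. Their mean counts were at least 89.8-fold and 59.1-fold higher. Recurring replicate 1 weighed most in these folds, and without it they were 17.5-fold for Itgav, 53.8-fold for Dck and 19.4-fold for Mypop. The folds leave out the spread between libraries. The 95% intervals of the log2 difference, which include it, began at 2.48 for Itgav, 2.61 for Dck and 2.37 for Mypop. Alg14, of protein glycosylation, was at 0.34 ± 0.69 and 7.24 ± 1.78. Adamts1, a secreted protease that cleaves proteoglycans, was at 0.52 ± 1.03 and 7.78 ± 3.38. The lysosomal acid ceramidase gene Asah1 was read in all 8 libraries, at 9.11 ± 1.33 and 11.39 ± 0.56, a difference of 2.28 (95% interval 0.89 to 3.67).

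The 6 lower genes also missed it. The clustered protocadherin Pcdhgc5 was at 6.83 ± 1.69 in Day 0 cells and at 0 reads in the 4 Recurring libraries, at least 63.1-fold lower, and at least 40.3-fold without Day 0 replicate 3. Socs5, of cytokine signalling, was at 8.87 ± 2.15 and 0.35 ± 0.69, and Isg20l2, an exonuclease gene, at 7.33 ± 2.14 and 0.26 ± 0.52. The zinc finger gene Zfp12 was at 8.96 ± 0.41 and 1.50 ± 3.01, with reads in 1 of the Recurring libraries. Tgfbrap1, of endosomal transport, was at 8.78 ± 1.11 and 1.36 ± 2.72, and Tcp11l2 at 8.85 ± 1.01 and 1.81 ± 2.33.

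**Figure D1:**
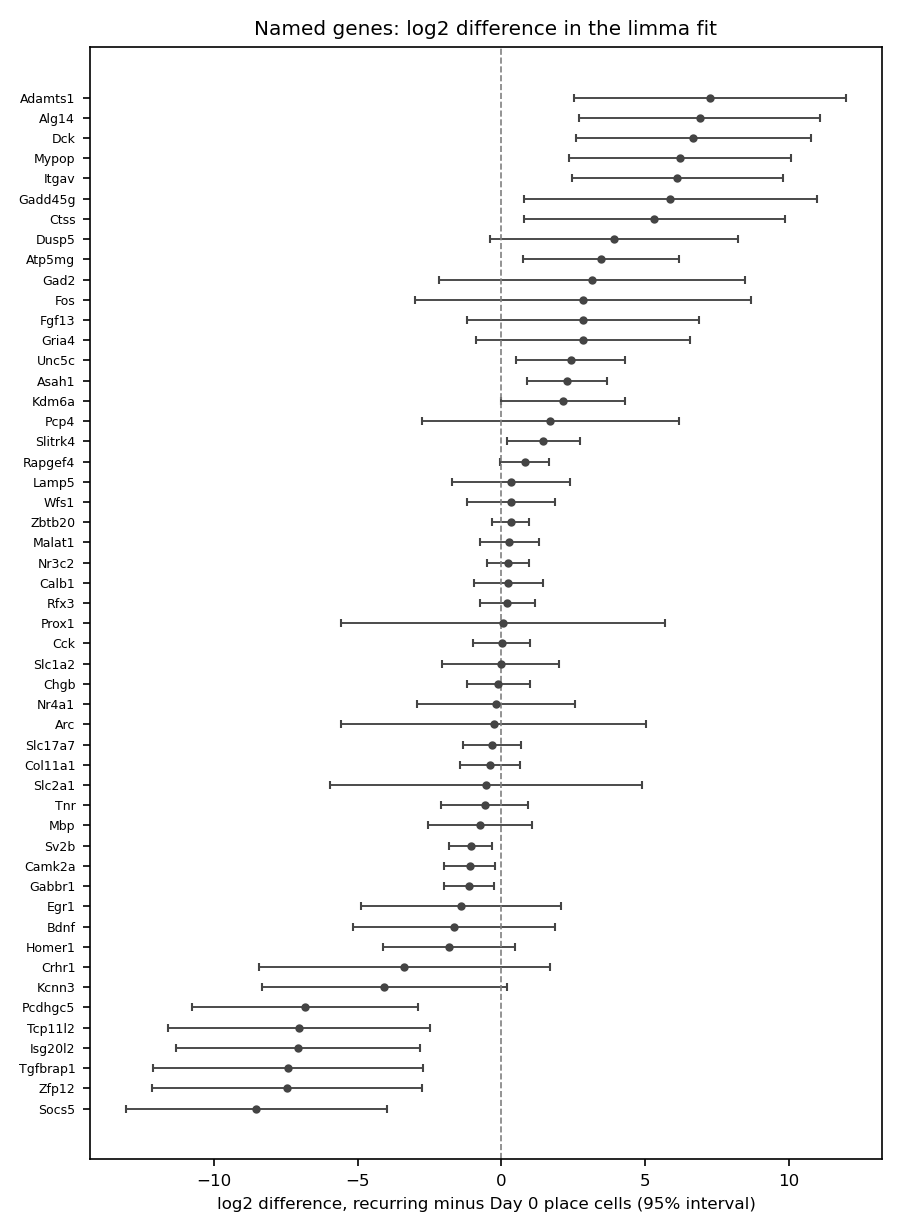
Difference in log2(normalized count + 1), Recurring minus Day 0, for tested genes named by the fixed rule, with bars for the 95% interval (4 libraries per group). None passed the adjusted threshold, and differences for genes at 0 in a group depend on the pseudocount.

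Precision varied with gene level. The median standard error was 1.78 log2 units over all tested genes and 0.465 in the 1108 genes with the highest means. The 95% interval lay within 1 log2 unit of 0 for 219 genes, 1.98% of those tested, all among those 1108. Over all tested genes 5056 were at 0 reads in at least 1 library, and in data simulated with this spread 2 of 40 changes of 4-fold were called.

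Genes induced by neuronal activity, whose early members respond within minutes of firing, did not separate the groups as lists. Of 17 tested rapid immediate early genes, 6 had higher and 11 lower means in Recurring cells, with an adjusted camera p of 0.920. Fos was at 3.30 ± 4.40 and 6.15 ± 4.44, Arc differed by -0.27 (SE 2.52), Egr1 by -1.41 (SE 1.65) and Nr4a1 by -0.18 (SE 1.31). Dusp5, a phosphatase gene of the same list, differed by 3.92 (SE 2.04). Npas4, an activity-induced transcription factor, was below the filter. It had 222, 99, 0 and 17 reads in Day 0 replicates 1 to 4 and 0 in each Recurring library. Its mean count was at least 24.9-fold lower, and at least 12.2-fold without Day 0 replicate 1. Fosb, chosen after its values were seen, had 189, 330, 0 and 190 reads against 0, a mean count at least 56.6-fold lower. Both genes were at 0 in Day 0 replicate 3 too, so these folds do not hold for every Day 0 library. Of 23 late activity-response genes 16 were higher and 7 lower, with an adjusted p of 0.486. Bdnf, a secreted growth factor, differed by -1.65 (SE 1.67), Homer1, a synaptic scaffold, by -1.83 (SE 1.09) and Gadd45g by 5.89 (SE 2.41). Recurring replicate 1 was low in several of these genes, and without it Homer1 differed by -0.31, Bdnf by 0.72 and Egr1 by 0.72. Without Recurring replicate 1 the late list was past the threshold, higher in Recurring cells, at an adjusted p of 0.0491, and at 0.855 with an estimated correlation. Without Recurring replicate 4 its adjusted p was 0.965, and its unadjusted p 0.555.

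**Figure D2:**
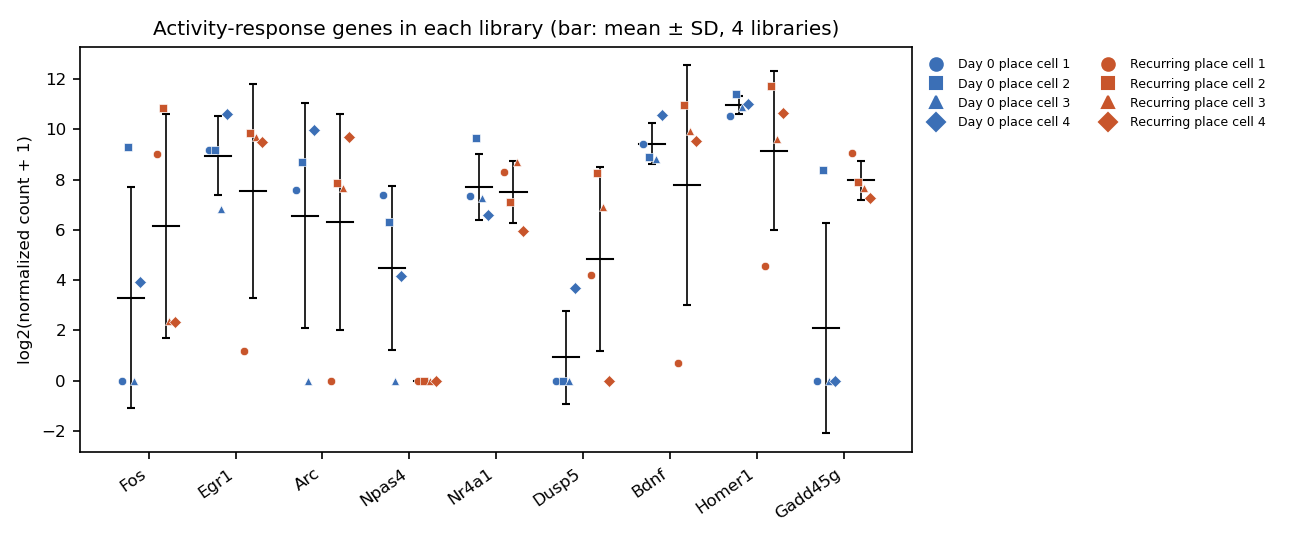
Log2(normalized count + 1) of 9 activity-response genes in each library, with bars for the mean and SD of 4 libraries per group. Npas4 was at 0 in all 4 Recurring libraries and in Day 0 replicate 3, and Egr1 and Bdnf were at 1.16 and 0.70 in Recurring replicate 1.

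Genes of the postsynaptic density, the scaffold under excitatory synapses, had more members lower than higher in Recurring cells and did not pass the adjustment. Of 42 tested members 14 were higher and 28 lower, and camera gave an unadjusted p of 0.0344 and an adjusted p of 0.332. Camk2a, the plasticity kinase, stood at 12.36 ± 0.58 in Day 0 and 11.27 ± 0.67 in Recurring cells (SD, n = 4), a difference of -1.09 (SE 0.42). Without Recurring replicate 1 this list was past the threshold at an adjusted p of 0.0495, and at 0.739 with an estimated correlation, while without Day 0 replicate 4 its adjusted p was 0.662. Among 22 genes of GABA receptors and the inhibitory postsynapse 8 were higher and 14 lower, with an adjusted p of 0.608. Gabbr1, a subunit of the metabotropic GABA receptor, stood at 11.93 ± 0.17 and 10.80 ± 0.59, a difference of -1.14 (SE 0.41). The 24 glutamate receptor genes were split 12 and 12, with an adjusted p of 0.958, and Gria4 differed by 2.83 (SE 1.77), or by 0.67 without Day 0 replicate 3.

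Presynaptic release genes numbered 23 higher and 14 lower of 37, with an adjusted p of 0.608. The synaptic vesicle gene Sv2b stood at 12.63 ± 0.14 in Day 0 and 11.57 ± 0.58 in Recurring cells (SD, n = 4), a difference of -1.06 (SE 0.35). Synaptic adhesion molecules numbered 32 higher and 29 lower of 61 (adjusted p of 0.677), with Slitrk4 different by 1.47 (SE 0.60). Axon and dendrite guidance genes numbered 14 and 11 of 25 (adjusted p of 0.920), with the netrin receptor gene Unc5c different by 2.42 (SE 0.90). In the extracellular matrix list 7 were higher and 10 lower of 17, the median difference was -0.15, the mean 0.65 and the camera direction up (adjusted p of 0.920).

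Among ion channels, potassium and HCN channel genes numbered 13 higher and 23 lower of 36 (adjusted p of 0.558), with the calcium-activated channel gene Kcnn3 different by -4.07 (SE 2.02). Sodium and calcium channel genes numbered 13 and 19 of 32 (adjusted p of 0.920), with Fgf13, a modulator of sodium channels, different by 2.84 (SE 1.91), or by 0.98 without Day 0 replicate 3. Genes of cAMP and CREB signalling numbered 21 and 19 of 40 (adjusted p of 0.608), with Rapgef4 different by 0.82 (SE 0.40). Endocannabinoid and neuromodulator receptor genes numbered 10 and 11 of 21 (adjusted p of 0.920), with Crhr1 different by -3.37 (SE 2.40). Chromatin regulators numbered 27 and 25 of 52 (adjusted p of 0.922). Kdm6a, a histone demethylase gene that escapes X inactivation, differed by 2.15 (SE 1.02). Nuclear-encoded oxidative phosphorylation genes numbered 41 and 33 of 74 (adjusted p of 0.608), with Atp5mg different by 3.46 (SE 1.29). Without Recurring replicate 1 that list was past the threshold, higher in Recurring cells, at an adjusted p of 0.0491, and at 0.855 with an estimated correlation, while without Recurring replicate 4 its direction was down (adjusted p of 0.965).

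Over all lists camera called 0 of the 29 tested, with 3 at an unadjusted p under 0.05, and the lowest adjusted p was 0.332. With an estimated correlation it was 0.932 and by fry 0.974, so no call was there to be held or lost. Over all genes tested, 0 list members passed. Adjusted over the list alone, 2 did, both in the microglia list. That adjustment does not allow for the number of lists, so these 2 are not counted as calls.

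Markers of glia were unevenly spread over libraries. Microglia markers, 4 of them tested, had 3 members higher in Recurring cells (unadjusted camera p of 0.0234, adjusted p of 0.332). Ctss, a lysosomal protease, differed by 5.33 (SE 2.15, adjusted p over the list alone of 0.0483). The complement gene C1qb, chosen after its values were seen, differed by 6.87 (SE 2.26, adjusted p over the list alone of 0.0302). Both had an adjusted p of 0.981 over all genes. Over the list alone C1qb missed the threshold without Day 0 replicate 3, at 0.0769. Ctss missed it at 0.104 without Day 0 replicate 3, 0.0698 without Day 0 replicate 4, 0.0605 without Recurring replicate 1, 0.0918 without Recurring replicate 2 and 0.0859 without Recurring replicate 4. With library weights Ctss differed by 3.20 and was at 0.117 over the list alone. The microglia level was 2.57 ± 1.08 in Day 0 and 4.81 ± 1.89 in Recurring cells (n = 4, exact permutation p = 0.0857, adjusted p = 0.600), with 7.09 in Recurring replicate 4. Astrocyte markers had 9 of 13 tested members higher (unadjusted camera p of 0.0146, adjusted p of 0.332), and their level was 8.80 in Recurring replicate 1. Plpp3 and the glutamate transporter gene Slc1a3, chosen after their values were seen, differed by 6.83 (SE 2.14) and 3.90 (SE 1.48), and Slc1a2, another, by -0.02 (SE 0.97). The astrocyte list was past the threshold without Recurring replicate 3 (adjusted p of 0.0453, 0.959 with an estimated correlation) and without Recurring replicate 4 (adjusted p of 0.00976, 0.809 with an estimated correlation). Without Recurring replicate 1, the library highest in these markers, its unadjusted p was 0.214 and its adjusted p 0.626.

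**Figure D3:**
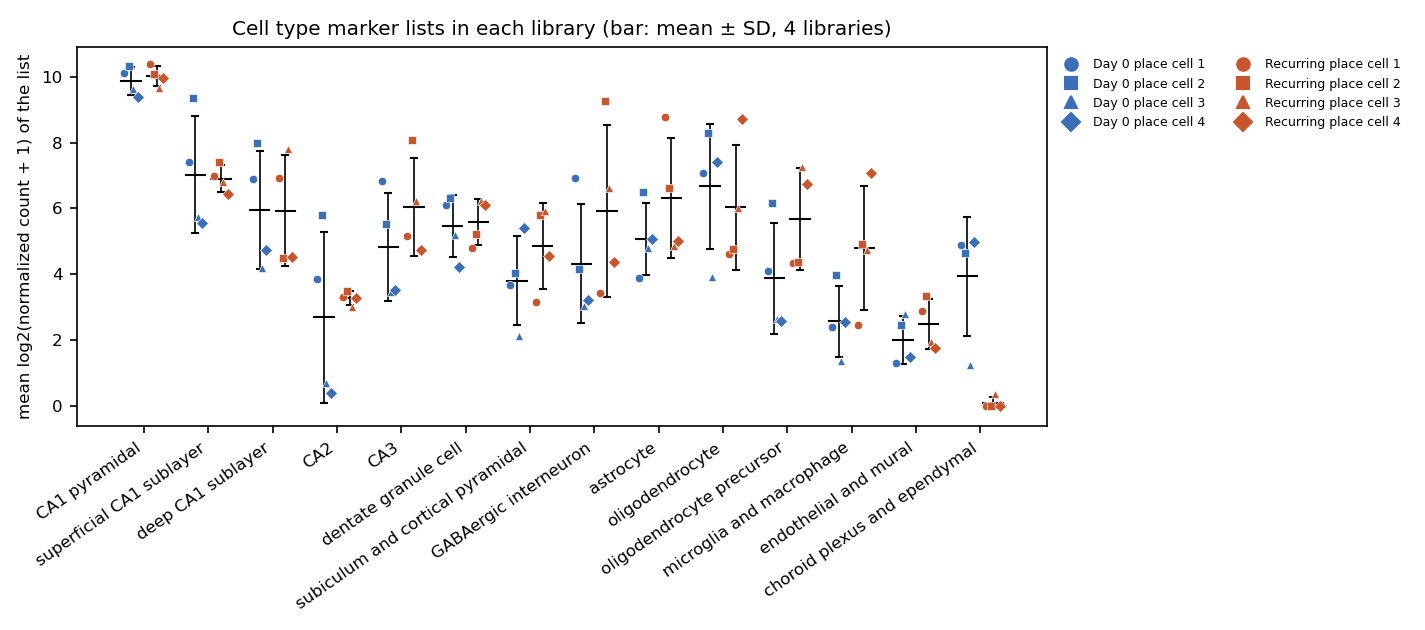
Mean log2(normalized count + 1) of each cell type marker list in each library, with bars for the mean and SD of 4 libraries per group. Interneuron markers were at 9.28 in Recurring replicate 2 and astrocyte markers at 8.80 in Recurring replicate 1.

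Markers of interneurons were at 9.28 in Recurring replicate 2 and between 3.02 and 6.92 in the other libraries, with 7 of 9 tested members higher in Recurring cells (adjusted p of 0.574). Gad2, of GABA synthesis, differed by 3.17 (SE 2.53) and Cck, a peptide also made by pyramidal neurons, by 0.01 (SE 0.47). Oligodendrocyte markers numbered 3 higher and 8 lower of 11 (adjusted p of 0.677), with the myelin gene Mbp different by -0.73 (SE 0.86). Oligodendrocyte precursor and endothelial markers had 3 tested members each, too few for a list test, with levels of 3.87 and 5.69, and of 2.00 and 2.48, in Day 0 and Recurring cells. Their genes Tnr and Slc2a1 differed by -0.57 (SE 0.72) and -0.54 (SE 2.57). Of the choroid plexus and ependymal list 3 of 11 genes were in the table, Kl, Foxj1 and Dnah12, and none reached the filter. These 3 genes were named after their values were seen. Their level was 3.93 ± 1.81 in Day 0 and 0.087 ± 0.174 in Recurring cells (n = 4, exact permutation p = 0.0286, the smallest possible, adjusted p = 0.400). In the limma fit with no filter, the 3 genes differed by -4.64, -3.85 and -3.04. Each was at an adjusted p of 0.0329 over the list alone, and 0 genes passed over all genes. The microglial gene Cx3cr1 was not in the table and was not analysed here.

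Other hippocampal neuron types gave no list past the threshold. Superficial CA1 markers numbered 4 higher and 2 lower of 6 (adjusted p of 0.922), with the mineralocorticoid receptor gene Nr3c2 different by 0.24 (SE 0.35). Deep CA1 markers were split 2 and 2 (adjusted p of 0.920) with a median of 0.27 but a camera direction of down, and Col11a1 differed by -0.38 (SE 0.50). CA3 markers numbered 4 and 3 of 7 (adjusted p of 0.608), with Chgb different by -0.11 (SE 0.52). Dentate granule cell markers numbered 8 and 4 of 12 (adjusted p of 0.677), with Rfx3 different by 0.21 (SE 0.46) and Prox1 by 0.06 (SE 2.67). The 4 tested subiculum and cortical markers were all higher (adjusted p of 0.920), with Lamp5 different by 0.35 (SE 0.97). CA2 markers had 2 tested members, with Pcp4 different by 1.70 (SE 2.12).

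Library checks did not separate the groups at the threshold. Heat shock and dissociation genes numbered 7 higher and 10 lower of 17 (adjusted p of 0.920), nuclear noncoding RNAs 5 and 7 of 12 (adjusted p of 0.608) and cytosolic ribosomal protein genes 48 and 28 of 76 (adjusted p of 0.574). Malat1 stood at 17.76 ± 1.56 and 18.05 ± 0.34, a difference of 0.28 (SE 0.49). Mitochondrially encoded genes numbered 6 and 3 of 9 (adjusted p of 0.486), and their share of reads was 0.0279% ± 0.0209 in Day 0 and 0.0638% ± 0.0416 in Recurring cells (n = 4, exact permutation p = 0.171). The 10 most abundant genes took 8.91% ± 3.10 and 8.66% ± 0.526 of reads (n = 4, exact permutation p = 0.886). Depth, the sum of deposited values and genes detected gave exact permutation p values of 0.514, 0.371 and 0.8, and all 7 measures had an adjusted p of 0.886. Xist, the RNA that coats the inactive X chromosome, had 9263 and 9072 reads in Day 0 replicates 1 and 2 and 15633 and 13236 in Recurring replicates 1 and 2, and at most 67 in the others. Y-linked genes had 11840 and 15832 reads in Day 0 replicates 3 and 4, 17596 and 14618 in Recurring replicates 3 and 4, and 0 in the others. The X-inactivation and Y-linked lists had 1 and 3 tested members, too few for a list test, and 2 libraries of each pattern stood in each group.

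Libraries of the same group did not correlate more closely than libraries of different groups. Pearson's r across genes, which are not independent replicates, ranged from 0.398 to 0.603 over the 28 pairs, with a median of 0.460. The mean was 0.472 ± 0.0526 within groups and 0.475 ± 0.0558 between them (SD over 12 and 16 pairs, exact permutation p = 0.771, one-sided).

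**Figure D4:**
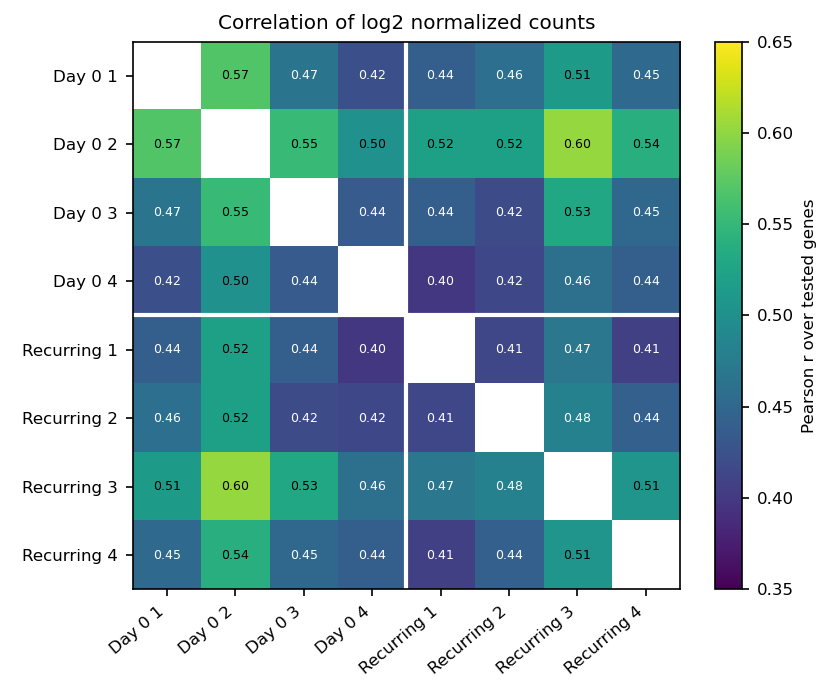
Pearson's r of log2(normalized count + 1) across tested genes for each pair of the 8 libraries. Values ranged from 0.398 to 0.603, with no block of higher values within either group.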

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

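The comparison of correlation within and between groups was planned, but its use below to weigh a group difference, and the tests of the number of genes detected, were chosen after the results were seen. The tests of depth, of few RNA molecules and of interneuron and astrocyte genes were set down before their results were seen. Within each group of 4 libraries, a value was picked out when it stood far from the other 3 relative to the group's range. C1qb, Plpp3 and Slc1a3 were added to this search after their values were seen. Of 189 groups of values examined 25 were picked out. In 11 of the 25 the other 3 libraries were all at 0, which picks out any value above 0, and 14 had no such ties. Chance picks out about 1 in 20 groups only where values are not tied, so the total has no chance value to be set against.

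Several genes named for their small p were at 0 in 3 libraries and above it in 1, on the log2 scale. In Day 0 replicate 2 these were Alg14 at 1.38, Adamts1 at 2.07, Gadd45g at 8.36 and C1qb at 5.68, and in Day 0 replicate 4 Dusp5 at 3.70. In Recurring replicate 3 they were Isg20l2 at 1.04, Zfp12 at 6.01 and Tgfbrap1 at 5.44. In Recurring replicate 2 Socs5 was at 1.39 and in Recurring replicate 4 Kcnn3 was at 3.72. Socs5 was also low in Day 0 replicate 2, at 5.66 against 9.76 to 10.26 in the other Day 0 libraries.

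Other genes were far from their group in 1 library. Gria4 was at 0 in Day 0 replicate 3 against 7.81 to 9.20, Wfs1 at 7.55 there against 9.94 to 10.42, and Slc1a3 at 1.31 in Day 0 replicate 1 against 7.42 to 8.50. In Recurring replicate 1 Pcp4 was at 0 against 5.16 to 5.88, Egr1 at 1.16 against 9.48 to 9.84, Bdnf at 0.70 against 9.55 to 10.96, and Slc1a3 at 12.99 against 9.07 to 9.67. Fgf13 was at 9.81 in Recurring replicate 2 against 7.79 to 8.13, Cck at 10.34 in Recurring replicate 3 against 11.08 to 11.11, and Slc1a2 at 6.00 in Recurring replicate 4 against 11.04 to 11.74. Among lists, sodium and calcium channels averaged 9.55 in Recurring replicate 3 against 9.15 to 9.21. Choroid plexus and ependymal markers averaged 1.23 in Day 0 replicate 3 against 4.63 to 4.99, and 0.35 in Recurring replicate 3 against 0. The X-inactivation genes averaged 0 in Recurring replicate 4 against 5.71 to 6.69.

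Libraries correlated weakly by Pearson's r, with a median of 0.460 over all pairs and a mean of 0.472 within groups. The tables argue against too few reads, as far as counting error goes, since reads redrawn at the same depth as if independent gave a median r of 0.999 with their own library. They argue against the difference between Day 0 and Recurring cells as its source, since r was low within groups too and the mean within minus between was -0.00298. A candidate explanation that stays open is few RNA molecules per library: the slope of squared variation on mean level across genes was -0.677, where sampling of molecules alone gives a slope near -1. The median coefficient of variation was 112% for genes with a mean of 100 to 300 and 28.7% at 10000 or more, against 7.35% and 0.854% from counting reads, and differences between animals or cells were not tested.

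Interneuron markers were at 9.28 in Recurring replicate 2, where 10 of the 15 genes of that list had their highest value. The number of genes detected argues against a richer library as the cause, since 4 libraries had more. RNA of interneurons may be the source. Of 28 interneuron genes set down outside that list 11 were in the table, and 5 of these were highest there. The 5, named after their values were seen, were Alk, Nr2f2, Rab3b, Rbms3 and Zfp536. Random genes of like level gave a median of 2 and p = 0.0194 by permutation of 10000 gene sets. That p takes genes as independent of each other and does not measure the spread between libraries. Tagging of chosen nuclei should leave interneurons out, and pyramidal neurons also express some of the interneuron genes. No biological explanation was tested, since the design gives none for 1 library.

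Astrocyte markers were at 8.80 in Recurring replicate 1, where 8 of the 17 genes of that list had their highest value. The number of genes detected argues against a richer library, since 6 libraries had more. RNA of astrocytes may be the source. Of 38 astrocyte genes set down outside that list 35 were in the table, and 11 of these were highest there. Random genes of like level gave a median of 5 and p = 0.0062 by permutation of 10000 gene sets. This p too takes genes as independent of each other and does not measure the spread between libraries. Among abundant astrocyte genes Slc1a3 was at 12.99 in that library, and Slc1a2 at 11.74, also its highest value, against 10.01 ± 0.46 in Day 0 cells (SD, n = 4). Slc1a2 was not particular to that library. Its normalized count was 3418 there, 2297 and 2111 in Recurring replicates 2 and 3, and 62.9 in Recurring replicate 4. No biological explanation was tested, and tagging of chosen nuclei should leave astrocytes out.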

How the results depend on the processing

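The deposited values as they stand, voom, the Y-linked covariate and leaving out Recurring libraries 1 and 2 together (chosen from their marker levels), the least folds without 1 library and the alternatives for counts over a list alone were added after the data were seen. Leaving out Recurring libraries 1 and 2 removed both Recurring libraries high in Xist. The Recurring libraries left both had Y-linked reads, while Day 0 held both patterns. That alternative therefore mixes the group difference with the sex-linked pattern. The planned edgeR quasi-likelihood and DESeq2 fits were not run although whole reads were recovered, because the deposited unit is not a count; voom on the recovered reads stood in their place. Over 22 alternatives limma called 0 genes, with 290 to 650 at an unadjusted p under 0.05, except that without a variance trend it called 2. Over 24 alternatives for the lists 0 were called, except 2 without Recurring libraries 1 and 2, and, leaving out 1 library at a time, 0 to 3: 3 without Recurring replicate 1, 1 without Recurring replicate 3 and 1 without Recurring replicate 4. The 2 were the postsynaptic density list, lower, and nuclear-encoded oxidative phosphorylation, higher, at an adjusted p of 0.0119 each, and at 0.385 and 0.918 with an estimated correlation. Of 6 lists followed through the alternatives, adjusted p ranged from 0.0119 to 0.974 for these 2, from 0.0491 to 0.974 for late activity-response genes, from 0.00976 to 0.974 for astrocyte markers and from 0.1005 to 0.974 for mitochondrially encoded genes and, over the 19 alternatives that left it at least 4 tested members, for microglia markers. The oxidative phosphorylation list was followed only because an alternative had called it. Adjusted over the list alone, 0 to 6 list members passed over 22 alternatives, C1qb in 20 of the 21 that tested it (0.00567 to 0.0769) and Ctss in 12 of 22 (0.0231 to 0.214). Other genes named here passed over the list alone in at least 1 alternative. Plpp3 passed with a pseudocount of 5 (0.0452), with voom (0.0275) and without Day 0 replicate 2 (0.0275). Adamts1 passed with no variance trend (0.0346), with voom (0.0289) and with the Y-linked covariate (0.0439). Gabbr1 passed with library weights (0.0411), and Kl, Foxj1 and Dnah12 with no filter (0.0329). No marker level and no library measure passed under any alternative, nor, over all genes, did any of the 54 genes named and tested. Differences of 16 of these changed sign under at least 1 alternative, 7 of them other than by leaving libraries out. None was past the threshold with either sign, and the cause was not tested.

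With equal library sums Cck differed by -0.033 and Prox1 by -0.018, and with quantile normalization by -0.027 and -0.92. With library weights the differences were -0.039 for Rfx3, -0.16 for Cck, -0.21 for Fos, 0.030 for Arc, -0.39 for Calb1 and -1.38 for Prox1. With genes detected as a covariate they were -0.020 for Cck and 0.0042 for Arc. With the deposited values they were 0.076 for Slc1a2 and -0.069 for Prox1, and the deep CA1 level differed by 0.0082. With voom Slc1a2 was at 0.12 and Prox1 at -0.30, and with the Y-linked covariate Slc1a2 was at 0.18. Without Recurring libraries 1 and 2, differences were 0.97 for Crhr1, -0.40 for Rfx3, -0.17 for Cck, 2.10 for Arc, 0.63 for Egr1, 0.31 for Bdnf and -0.080 for Calb1. The astrocyte list then turned down, at an unadjusted p of 0.526. As shares of reads in percent, superficial CA1 markers differed by 0.0105, CA2 markers by -8.89e-05 and CA3 markers by -0.0181. Over the 500 most variable genes the mean r within minus between groups was 0.0101.

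Leaving out 1 library at a time, the unadjusted camera p of the oxidative phosphorylation list ranged from 0.00170 to 0.722, and its direction was down without Recurring replicate 4 (0.562). Differences of genes then ranged from -0.50 to 0.39 for Chgb, -0.049 to 0.53 for Rfx3, -0.30 to 0.85 for Lamp5, -0.18 to 0.26 for Cck and -0.61 to 1.31 for Slc1a2. They ranged from -2.55 to 1.30 for Slc2a1, -2.46 to 1.84 for Arc, -2.17 to 0.72 for Egr1, -0.57 to 0.46 for Nr4a1, -2.71 to 0.72 for Bdnf, -0.30 to 0.66 for Wfs1, -0.19 to 0.59 for Calb1, -0.43 to 0.72 for Malat1 and -1.54 to 1.68 for Prox1. Of the 54 genes, 28 moved by over 1.5 times or changed sign without 1 library, and 14 of these changed sign. The others of the 28 ranged from 0.67 to 3.74 for Gria4, 0.98 to 4.15 for Fgf13, -4.91 to -1.93 for Crhr1, 0.13 to 0.53 for Zbtb20, 0.049 to 0.47 for Nr3c2, -0.70 to -0.10 for Col11a1 and -1.16 to -0.11 for Tnr. They ranged from 1.75 to 4.12 for Fos, -2.69 to -0.31 for Homer1, -0.65 to -0.072 for Slc17a7, 1.86 to 4.84 for Gad2, -1.45 to -0.078 for Mbp, 2.22 to 4.61 for Slc1a3 and 0.92 to 3.06 for Pcp4. Levels differed by -0.0039 to 0.31 for CA1, -0.61 to 0.66 for superficial CA1, -0.64 to 0.66 for deep CA1, -0.18 to 1.62 for CA2 and -0.28 to 0.42 for dentate markers. Genes detected differed by -668 to 361.7, the share of the 10 top genes by -1.45 to 0.894, Xist by -1.63 to 3.56, Y-linked level by -0.77 to 3.35 and r within minus between by -0.0123 to 0.00967. Over all its alternatives the lowest exact permutation p of the last was 0.229. The counting of reads set little of the spread, since reads redrawn as if each were independent gave a median r of 0.999 with their own library. This covers counting error only, says nothing of how many molecules were sampled, and does not measure the precision of a group difference.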

Other observations

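The counts of splits for genes and lists past the threshold were chosen after those results were seen, as was that of genes at an unadjusted p under 0.05, and those for genes without overlap and genes read in one group only were set down before. That Xist and Eif2s3y were called was looked up afterwards. The 8 libraries can be split into equal groups in 35 ways. A split by sex-linked genes, and not the study's own, was the only one in which limma called any gene: Day 0 replicates 1 and 2 with Recurring replicates 1 and 2, against the other 4 libraries. It called Xist, at 13.05 and 2.52 (log2, SE of the difference 1.44, adjusted p = 0.0106), and Eif2s3y, a Y-linked translation factor gene, at 0 and 13.46 (SE 1.53, adjusted p = 0.00198). Both were chosen after their values were seen.

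The study's own split gave 0 genes, and the highest other gave 2. For lists it gave 0, the highest other gave 6, and 22 splits gave at least 1 list. Against a count of 0 each of the 35 splits gives as many whatever the data, so for these counts the splits test nothing. They do show that camera at its preset correlation often called lists under other groupings, with a median of 1 list. The lists called above with libraries left out are to be read with that limit. In 267 genes, 137 higher and 130 lower in Recurring cells, the libraries of the groups did not overlap. This was 2.41% of genes tested where chance gives 2.86%, and 30 of the splits gave as many. The highest other, with 416, was the split by sex-linked genes described above. With the deposited values, an alternative added after the data were seen, there were 233. In 30 genes, 17 in Recurring only and 13 in Day 0 only, reads were found in all libraries of one group and none of the other. All 35 splits gave as many, with 85 in the highest other, and with detection of each gene set at 10 reads, for this count an alternative added after the data were seen, there were 29. Chance cannot be excluded for the counts of 267 and 30, and genes such as Itgav and Pcdhgc5 belong to the last set.

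Apod, an apolipoprotein gene chosen after its values were seen, had 80282 reads in Recurring replicate 2, 0.656% of that library (95% exact interval 0.652 to 0.661), and between 353 and 3966 reads in the other libraries.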
